A study of Mus musculus with 9 samples.

How the data were processed

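Whole-lung total RNA of male mice exposed to air, IQOS aerosol or cigarette smoke (CS) was measured on one-colour Agilent arrays, with 3 arrays per group. Per the labels, RNA was extracted with miRNeasy kits and Cy3-labelled cRNA was made from 100 ng. The spot intensities were made by the authors with Agilent Feature Extraction 10.7.1.1, per the file headers, which records a background-subtracted and detrended signal for each spot with a positive floor and no normalization between arrays. Each array has its own file. The deposited series matrix holds a linear ratio for 56745 probes, each value divided by its array's 75th percentile. Its scale was found from the values, since no label states it. Its 9 column medians were 0.114, 0.116, 0.121, 0.12, 0.118, 0.117, 0.12, 0.12 and 0.12, with no log, no centring of probes and larger values for brighter spots.

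Changes were computed from the spot intensities. Of 62976 spots per array, 59305 were not controls and held 56605 probes, 300 of them with 10 spots. Spots marked by the software as outliers were left out and the log2 signals of a probe's spots were averaged. Each array was scaled by subtracting the log2 of its 75th percentile over non-control probes. The 75th percentile signal lay between 973.3 and 1098 units, and 0 spots were saturated. A probe was tested if each group had a value on at least 2 arrays and if, in at least 1 group, it was well above background on every array with a value, which left 37258 probes. Signal relative to background, not read depth, sets the precision of an array value, and beyond that the number of arrays limits it. The planned mean signal and gene name columns are absent from the files, so the median signal columns were used for the background alternative and probes were named by matching their accessions to a table of mouse RefSeq genes. In this way 32994 probes (58.3%) received 1 of 22911 symbols, of which 16593 were tested.

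Groups came from the labels. The contrasts CS minus air, IQOS minus air and IQOS minus CS were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, all 9 arrays, files read with the data.table package, version 1.17.8), and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. A gene with several probes was represented by the probe with the highest mean signal. Probes of 1 gene were called in opposite directions in 2 of 328 genes with at least 2 called probes for CS against air (Acot5 and Speg), 2 of 24 for IQOS against air (Chd4 and Speg) and 4 of 209 for IQOS against CS (Dab2, Kif5b, Ptges and B3galnt2), named after their values were seen. For a probe not well above background in 1 group, the fold is a lower bound computed against the background limit. Gene lists for 45 pathways and cell types, with 862 different symbols of which 803 were tested, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 45 lists. For each list the genes called over all genes were counted, and again after adjusting over the list alone.

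The design, the gene lists, the rule for naming genes and the alternatives below were written before the data were examined. The rule named, in each comparison, the 10 genes with the largest positive and the 10 with the largest negative change among called probes whose groups did not overlap and which had a true symbol. It added up to 4 genes with the smallest p in each list described, and in every comparison Cyp1a1, Cyp1b1, Nqo1, Mmp12, Gpnmb, Cdkn1a, Bax, Fas and Bcl2. A few genes that the rule named are not reported here and are left out of counts of named genes. Genes named outside the rule are said to be named after their values were seen.

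The fit was tested on simulated data with 67, 67 and 66 of 37258 probes changed 1.5-fold, 2-fold and 4-fold. For CS against air 47.8%, 79.1% and 98.5% of these were recovered with 8 false calls, for IQOS against air 38.8%, 77.6% and 97% with 10 false calls, and for IQOS against CS 53.7%, 77.6% and 95.5% with 10 false calls. A list of 26 genes shifted 1.3-fold among 16593 genes was recovered in each comparison (camera adjusted p 3.21e-33, 2.29e-27 and 2.99e-27). The genes were simulated independently of each other, so the test of lists whose genes vary together was not examined in this way.

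The alternatives were normexp background correction with an offset of 50 on the median signals, quantile normalization, median centring, no filter on dim probes, a filter on all 9 arrays, the series matrix values, an intensity trend with robust eBayes, the replicate number as a block, array row as a covariate, the mean of all probes of a gene, only the arrays of the groups compared, a 2-fold minimum, an adjusted p under 0.1, camera with an estimated correlation, and each of the 9 arrays left out in turn. No setting moved the median change of all probes by more than 0.1 on the log2 scale. Slide could not be a covariate, since the IQOS arrays alone fill the second slide. The shared air arrays were allowed for by 100 simulated draws of unchanged groups. Outliers within groups were not tested, because groups of 3 arrays are too small.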

Results

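Gene expression was measured in whole lungs of male C57BL/6J mice with one-colour (Cy3) Agilent mouse arrays. The mice were 12 weeks old at the start and breathed fresh air, a 3.5% aerosol of IQOS (a heated tobacco product) or 3.5% cigarette smoke (CS) for 6 months. Each group had 3 arrays, called air 1 to 3, CS 1 to 3 and IQOS 1 to 3 after the replicate numbers in the labels. Between 64.3% and 68.8% of the 56605 probes were well above background on each array, with means of 66.1% ± 1.52 (SD, n = 3) in air, 65.9% ± 0.33 in CS and 67.7% ± 1.46 in IQOS. The number of arrays limits the precision of every value. The air and CS arrays lay on 1 slide and the IQOS arrays on another, so slide and IQOS exposure cannot be told apart. Within the slides the CS arrays lay in array row 2, the IQOS arrays in row 1, air 1 and air 2 in row 1 and air 3 in row 2. A fit with array row as a covariate therefore takes its row term from the air arrays alone, with air 3 as the only one in row 2. The labels do not state that each array came from a separate animal, so p-values measure the spread between these samples. Changes are log2 fold changes ± standard error from limma with 3 arrays per group, adjusted by the Benjamini-Hochberg method over 37258 probes. Gene lists were tested with camera, and the adjusted p of each list that passed is given with a preset correlation and with a correlation estimated from the data. Lists that did not pass are given with the preset one, and no list passed with the estimated one. Where a call is said to end without several arrays, they were left out 1 at a time. The series asks which genes and pathways differ between the exposures and its title names apoptosis and emphysema.

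**Figure D1:**
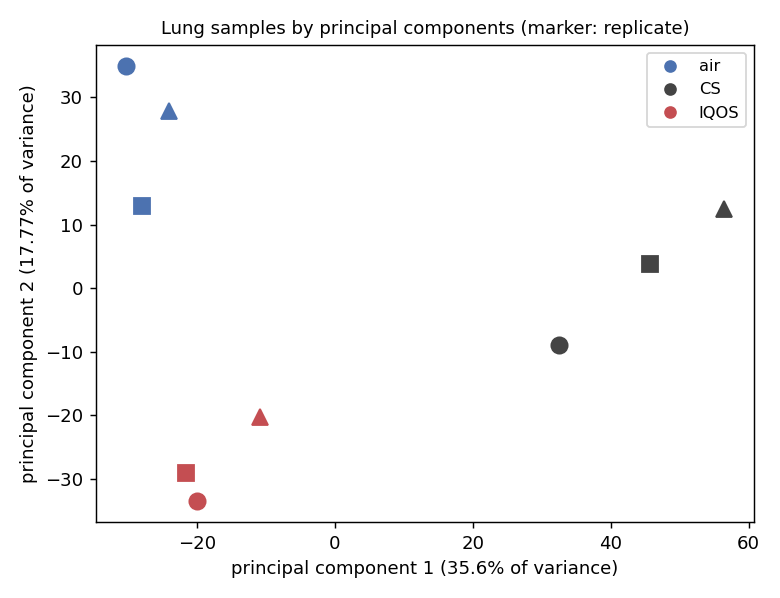
Principal component scores of the 9 arrays over all tested probes, component 1 (35.6% of the variance) on the x axis and component 2 (17.8%) on the y axis, each point 1 array coloured by group. The CS arrays lie between 32.5 and 56.5 on component 1, and the air arrays (12.9 to 34.9) and IQOS arrays (-33.4 to -20.3) lie apart on component 2.

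The comparison of CS with air addresses what long smoke exposure changes in the lung. Cyp1a1, whose enzyme oxidises polycyclic aromatic hydrocarbons and which is switched on by the aryl hydrocarbon receptor (AhR), rose 479.8-fold (log2 8.91 ± 1.09, adjusted p 0.00607). That standard error pools the spread of all groups, which for Cyp1a1 was widest among the IQOS arrays. Cyp1b1, another target of the receptor, rose 44.7-fold (log2 5.48 ± 0.27, adjusted p 0.000483). The receptor's repressor Ahrr rose at least 38.9-fold, with an air signal not well above background on any array (adjusted p 0.00055), and Aldh3a1 rose by 2.82 ± 0.21. Of 15 AhR and phase I enzyme genes measured, 6 rose and 1 fell, against 8 and 1 adjusted over the list alone. The gene that fell, Fmo1 (-0.66), was named after its value was seen. The list's median was 0.45 (adjusted p 3.64e-05 with the preset and 0.448 with the estimated correlation), and 0.29 without CS 1.

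The NRF2, glucocorticoid-responsive and immediate early lists also rose with CS. The glutathione transferase Gstp1 rose by 0.79 ± 0.08 (adjusted p 0.0036), Nqo1 by 2.56 ± 0.41 (adjusted p 0.0135), Txnrd1 by 0.91 ± 0.15 and Akr1b8 by 1.32 ± 0.25. Leaving out 1 array ended the calls of Nqo1 (adjusted p 0.0525 without air 1), Txnrd1 (0.0555 without CS 2) and Akr1b8 (up to 0.0696 without air 1, air 2, CS 2 or CS 3). Of 26 NRF2 genes, 9 rose and 0 fell, 11 and 1 adjusted over the list alone, with 15 at an unadjusted p under 0.05 in limma (median 0.59, adjusted p 1.17e-06 with the preset and 0.664 with the estimated correlation). The metal-binding proteins' genes Mt1 and Mt2 rose by 1.63 ± 0.11 and 1.55 ± 0.14, the cochaperone gene Fkbp5 by 1.64 ± 0.19 (adjusted p 0.00539) and the iron-scavenger gene Lcn2 by 1.85 ± 0.25. They belong to the glucocorticoid-responsive list, of whose 15 genes 6 rose and 1 fell, 6 and 2 adjusted over the list alone. The gene that fell, Sult1a1 (-0.39), was named after its value was seen. That list's median was 0.31 (adjusted p 0.00612 with the preset and 0.664 with the estimated correlation). The median was 0.19 without air 1, 0.48 without air 2 and 0.21 without CS 1, where the adjusted p was 0.051. Among 20 immediate early genes 3 rose and 0 fell, with 10 at an unadjusted p under 0.05 in limma, and 7 and 0 adjusted over the list alone. Ier3 rose by 1.13 ± 0.13, Junb by 0.96 with its call lost without air 1, air 3 or CS 3 (adjusted p up to 0.0598), and Egr2 by 0.75 with its call lost without any array but CS 1 and CS 2 (up to 0.117). The median of this list was 0.62 (adjusted p 7.14e-05 with the preset and 0.665 with the estimated correlation).

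Further genes among the 10 largest rises were Awat1, Moxd2, Cd177, Cd200r2, Stra6l, Acod1 and Cxcr1. Awat1 (wax ester synthesis) rose at least 12.01-fold and Moxd2 at least 10.8-fold, neither well above background in air, and Moxd2 had a value on 2 CS arrays, since an outlier spot was left out, and was above background on both. Cd177, a neutrophil surface antigen, rose by 5.04 ± 0.96 and Cd200r2 by 4.90 ± 0.45, each above background on 1 of the 3 air arrays. The retinol transporter relative Stra6l rose by 4.06 ± 0.19 (adjusted p 0.000483), the itaconate-making enzyme gene Acod1 by 3.78 ± 0.87 and the chemokine receptor gene Cxcr1 by 3.72 ± 0.52. The 10 largest falls were in Klhl14, Cyp26b1, Gmnc, Spon2, Fabp1, Kcna1, Nupr1, Lgr5, Hcar1 and Pabpc4l. The retinoic acid hydroxylase gene Cyp26b1 fell by 2.85 ± 0.45 (adjusted p 0.0126), the fatty acid binding protein gene Fabp1 by 1.95 ± 0.21 (adjusted p 0.00478), the stress regulator Nupr1 by 1.67 ± 0.16 (adjusted p 0.00327) and the matrix protein gene Spon2 by 2.31 ± 0.51. Klhl14 was at least 3.08-fold lower, Gmnc at least 2.27-fold, Pabpc4l at least 1.83-fold and Hcar1 at least 1.07-fold, none well above background in CS, and Hcar1 was above it on 2 of the 3 air arrays. Kcna1 fell by 1.73 and Lgr5 by 1.66, above background on 1 and 2 of the 3 CS arrays. Of these 20 genes, 12 kept their call without each of the 9 arrays in turn and 8 did not. The calls ended for Cd177 without air 1, air 3, CS 2 or CS 3 (adjusted p up to 0.0616) and for Acod1 without any air array, CS 2 or CS 3 (up to 0.116). The call of Gmnc ended without CS 2 (0.0545), that of Spon2 without air 1 or any CS array (up to 0.0818) and that of Kcna1 without any air array or CS 2 (up to 0.0691). They also ended for Klhl14 without any array but air 2 and CS 1 (up to 0.139), Lgr5 without any array but air 2 (up to 0.109) and Hcar1 without any array but CS 1 and IQOS 2 (up to 0.11).

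The 3 macrophage lists rose with CS. Gpnmb, a glycoprotein gene of lipid-laden macrophages, rose by 2.16 ± 0.18 (adjusted p 0.00223), the collagen- and elastin-cleaving cathepsin gene Ctsk by 2.12 ± 0.17 (adjusted p 0.00193), Cd68 by 1.53 ± 0.11 (adjusted p 0.00174) and Ctsd by 0.99 ± 0.07. Among 25 lysosomal and lipid-handling macrophage genes 14 rose and 0 fell, 19 and 1 adjusted over the list alone, with 20 at an unadjusted p under 0.05 in limma (median 0.45, adjusted p 5.91e-12 with the preset and 0.39 with the estimated correlation). Among 19 alveolar macrophage markers 9 rose, among them Itgax (1.07 ± 0.09) and Chil3 (1.36 ± 0.14), and 1 fell, Fabp1. Adjusted over the list alone 12 rose and 3 fell (median 0.36, adjusted p 0.000375 with the preset and 0.456 with the estimated correlation). Among 19 interstitial macrophage and monocyte markers 4 rose and 0 fell, 7 and 0 adjusted over the list alone, with 9 at an unadjusted p under 0.05 in limma. The Fc receptor gene Fcgr4 rose by 1.49 ± 0.18, and the list's median was 0.23 (adjusted p 0.00596 with the preset and 0.665 with the estimated correlation). That list did not pass with array row as a covariate (adjusted p 0.11).

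The neutrophil and cytokine lists rose as well. Of 19 neutrophil markers 4 rose and 0 fell, 12 and 0 adjusted over the list alone, with 13 at an unadjusted p under 0.05 in limma (median 1.64, adjusted p 2.77e-06 with the preset and 0.664 with the estimated correlation). The decoy interleukin-1 receptor gene Il1r2 rose by 3.50 ± 0.61 (adjusted p 0.0158), and the lectin gene Clec4d by 2.44 ± 0.54. Neither held without air 1 or CS 2 (adjusted p up to 0.0653 for Il1r2), and Clec4d also fell short without air 2, air 3 or CS 3 (up to 0.107). Of 26 cytokine and chemokine genes 10 rose and 0 fell, 14 and 0 adjusted over the list alone, with 16 at an unadjusted p under 0.05 in limma (median 0.80, adjusted p 7.56e-07 with the preset and 0.448 with the estimated correlation). Ccl6 rose by 1.47 ± 0.13, the neutrophil attractants Cxcl1 and Cxcl2 by 2.41 ± 0.31 and 1.96 ± 0.25, and the acute-phase gene Saa3 by 2.75 ± 0.40. Il6 rose by 2.34 ± 0.36 (adjusted p 0.012, and 0.0518 without air 1). The 24 elastin-degrading proteases and their inhibitors did not pass as a list (median 0.22, adjusted p 0.0508 with the preset and 0.664 with the estimated correlation). In that list 7 genes rose and 1 fell, 11 and 4 adjusted over the list alone. The metalloproteinase gene Adam8 rose by 1.95 ± 0.24 and the cathepsin gene Ctss by 0.72 ± 0.11, while the macrophage elastase gene Mmp12 changed by 1.24 ± 0.40 and did not pass (adjusted p 0.0843). The inhibitor gene Timp2 fell by 0.27 and Timp3 rose by 0.39, and both calls ended without air 2, air 3, CS 2 or CS 3 (adjusted p up to 0.101 and 0.0659), that of Timp2 also without air 1.

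The matrix and smooth muscle lists fell with CS. Fbn1, which encodes the scaffold of elastic fibres, fell by 0.81 ± 0.08 (adjusted p 0.00327), the elastin crosslinker gene Loxl1 by 1.01 ± 0.12, Col5a1 by 0.78 ± 0.10 and Col1a1 by 0.93 ± 0.15 (adjusted p 0.012). Of 28 matrix and fibroblast markers 10 fell and 0 rose, with the same counts adjusted over the list alone and 12 at an unadjusted p under 0.05 in limma (median -0.36, adjusted p 4.07e-06 with the preset and 0.664 with the estimated correlation). Of 14 smooth muscle and pericyte markers 3 fell and 0 rose, 7 and 0 adjusted over the list alone, with 9 at an unadjusted p under 0.05 in limma. The actin-nucleating Lmod1 fell by 0.73 ± 0.08, and Des by 0.56 with its call lost without each of the 9 arrays (adjusted p up to 0.0985). The median of this list was -0.43 (adjusted p 0.000194 with the preset and 0.664 with the estimated correlation). Among endothelial markers, which did not pass as a list (27 genes, 2 up and 5 down, 3 and 7 adjusted over the list alone, adjusted p 0.104), the apelin receptor gene Aplnr fell by 1.42 ± 0.13 (adjusted p 0.00278).

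The alveolar type II and club cell lists rose with CS, while the alveolar type I (adjusted p 0.873), ciliated (0.08), goblet (0.39) and squamous (0.875) lists did not pass. Of 20 alveolar type II markers 4 rose and 0 fell, 4 and 1 adjusted over the list alone, with 9 at an unadjusted p under 0.05 in limma (median 0.13, adjusted p 0.013 with the preset and 0.792 with the estimated correlation). The alarmin gene Il33 rose by 1.11 ± 0.17 (adjusted p 0.0114). The list did not pass with array row as a covariate (adjusted p 0.0544). Of 18 club cell markers 2 rose and 0 fell, 6 and 1 adjusted over the list alone, with 7 at an unadjusted p under 0.05 in limma (median 0.29, 0.18 without air 1, adjusted p 0.00447 with the preset and 0.713 with the estimated correlation). The genes that rose were Krt8 (0.65) and Hp (0.31), and neither held without any 1 of the air arrays, CS 2 or CS 3 (adjusted p up to 0.0849 and 0.0827). The B cell, adipocyte and cardiac muscle lists were lower. Of 18 B cell and plasma cell markers 4 fell and 0 rose, 10 and 0 adjusted over the list alone, with 10 at an unadjusted p under 0.05 in limma (median -1.12, adjusted p 0.00603 with the preset and 0.731 with the estimated correlation). The CD20 gene Ms4a1 fell by 1.54 ± 0.39 (adjusted p 0.046, up to 0.138 without any array but CS 1 and IQOS 2). Among 13 adipocyte markers 2 fell and 0 rose, 5 and 1 adjusted over the list alone, with 10 at an unadjusted p under 0.05 in limma (median -0.78, adjusted p 0.0318 with the preset and 0.792 with the estimated correlation). The adrenergic receptor gene Adrb3 fell by 0.78, a call lost without air 1, air 2, CS 1 or CS 2 (adjusted p up to 0.0909), and the lipid droplet gene Plin4 by 0.63, lost without any array but IQOS 2 (up to 0.149). The adipocyte list did not pass without air 2 (adjusted p 0.123), without CS 3 (0.0722) or with array row as a covariate (0.314). Of 15 cardiac muscle markers 0 passed over all genes or over the list alone and 2 had an unadjusted p under 0.05 in limma (median -0.51, adjusted p 0.0236 with the preset and 0.878 with the estimated correlation). The cardiac median was -0.79 without air 1, -0.30 without air 2 (adjusted p 0.172) and -0.24 without CS 3 (0.217). The list missed the threshold without air 3 too (0.0819).

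Few proapoptotic genes passed with CS. For comparison, 5.01% of all tested probes with a symbol were called higher and 6.24% lower. These RNA levels do not measure apoptosis itself. Trp53, which encodes p53, fell by 0.50 ± 0.07 (adjusted p 0.00801), and was the single gene called among 34 proapoptotic genes, over all genes and adjusted over the list alone (list median -0.01 against a mean of 0.04, adjusted p 0.869 with the preset correlation). The call of Trp53 ended with array row as a covariate (log2 -0.52, adjusted p 0.0806). Bax changed by 0.05 ± 0.07 (adjusted p 0.673), Fas by 0.02 ± 0.12 (adjusted p 0.92) and the antiapoptotic Bcl2 by -0.26 ± 0.23 (adjusted p 0.506). None of these passed. The direction of Fas flipped with quantile normalization and that of Bax with the mean of all probes. Of 19 antiapoptotic genes 4 rose and 0 fell, 5 and 1 adjusted over the list alone, with 8 at an unadjusted p under 0.05 in limma (median 0.14, adjusted p 0.0736). The survival kinase gene Pim1 rose by 1.01 ± 0.11 (adjusted p 0.00479) and Bcl2a1d by 0.59 ± 0.10 (adjusted p 0.0171, and 0.0705 without air 1). The others were Naip2 (0.48), lost without any array but IQOS 2 and IQOS 3 (adjusted p up to 0.117), and Birc3 (0.49), lost without any air or CS array (up to 0.104). Of 22 p53 target genes 2 fell and 0 rose, over all genes and adjusted over the list alone, with 5 at an unadjusted p under 0.05 in limma (adjusted p 0.875). They were Eda2r (-1.24, lost without any array but CS 1 and CS 3, adjusted p up to 0.125) and Rrm2b (-0.33, lost without any array but CS 1, up to 0.143). Cdkn1a changed by 0.41 ± 0.33 without passing (adjusted p 0.449). Among 17 clock genes 4 rose and 0 fell, the same counts adjusted over the list alone, with 8 at an unadjusted p under 0.05 in limma, led by Cry1 (0.97 ± 0.12) and Bhlhe40 (1.09 ± 0.15). The list did not pass (adjusted p 0.0513). That test looks for a shift of the whole list in 1 direction, so members that move in opposite directions can cancel.

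In limma 3840 probes passed between CS and air, 1725 higher and 2115 lower, for 2356 genes with a symbol, and 575 of them changed at least 2-fold, 406 higher and 169 lower. In each called probe the arrays of 1 group all lay above those of the other, which held for 35.1% of all probes where chance gives 10%. The count was 725 without air 1, 1958 without air 2, 1789 without air 3, 1063 without CS 2 and 1897 without CS 3. Of the called genes named by rule, 45 of 109 kept their call without each array. The count was 2966 from the air and CS arrays alone, which share a slide and 1513 without both air 2 and IQOS 3. With array row as a covariate it was 311, and 26 of the 109 genes kept their call, Ahrr, Cyp1b1, Gpnmb, Ctsk, Fbn1 and Mt1 among them. Cyp1a1 did not, though its change stayed at log2 8.71. Its standard error pools all 9 arrays, and its signal spread widely only in IQOS (-1.58, -1.46 and 3.09).

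**Figure D2:**
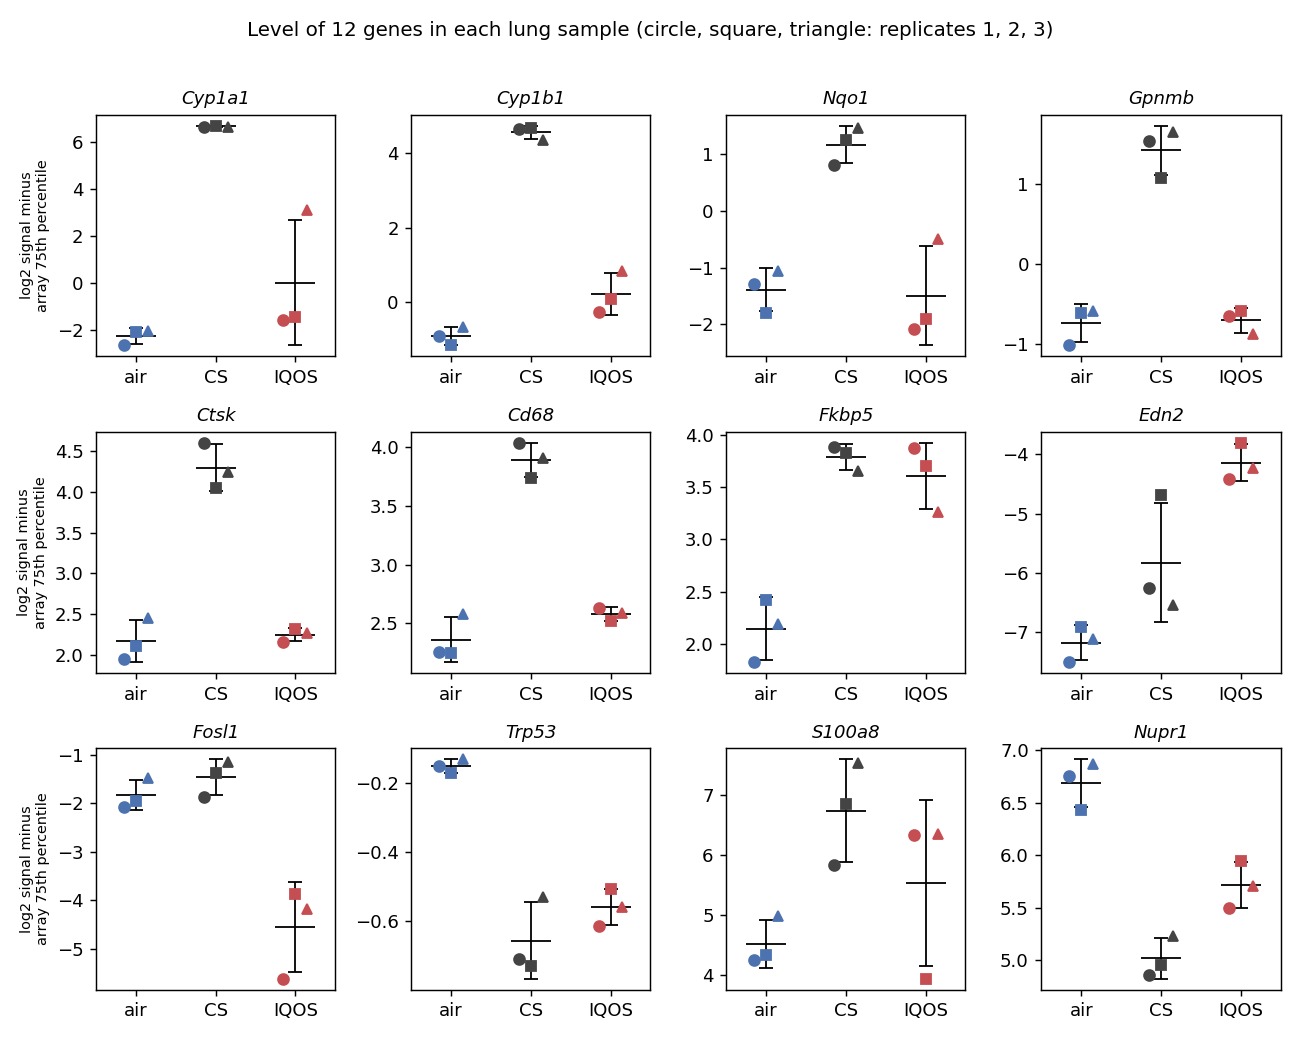
Log2 signal relative to the array's 75th percentile (y axis) of 12 genes in the air, CS and IQOS groups (x axis), with each array as a point (circle, square and triangle for replicates 1, 2 and 3), the group mean as a line and the SD as bars. Cyp1a1 lies between 6.64 and 6.68 on the CS arrays, between -2.62 and -2.06 on the air arrays, and at -1.58, -1.46 and 3.09 on the IQOS arrays.

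The comparison of IQOS with air addresses what the heated tobacco aerosol changes. The 10 largest rises were in Edn2, Plaat5, Bpifa3, D14Ertd670e, Doc2b, Fkbp5, Ramp3, Krtap10-10, Smg8 and Cmtm2b. The phospholipid-metabolising enzyme gene Plaat5 rose by 2.84 ± 0.26 (adjusted p 0.00543), and the cochaperone gene Fkbp5, which glucocorticoids induce, by 1.46 ± 0.19 (adjusted p 0.0121). Edn2, for an endothelin peptide, rose at least 2.27-fold and Bpifa3 at least 2.93-fold, neither well above background in air. The others rose by 1.90 ± 0.33 (D14Ertd670e), 1.84 ± 0.38 (the exocytosis gene Doc2b), 1.46 ± 0.25 (the receptor partner gene Ramp3, with a value on 2 air arrays), 1.45 ± 0.13 (Krtap10-10), 1.36 ± 0.13 (Smg8, above background on 1 of 3 air arrays) and 1.33 ± 0.14 (Cmtm2b). The largest falls were in Fosl1, Krt36, Atp13a5, Prdm8, Pabpc4l, Cgref1, Nnat, Nupr1, Pbp2 and Ccn5. The AP-1 subunit gene Fosl1 fell by 2.72 ± 0.43 (adjusted p 0.0217, above background on 2 of 3 IQOS arrays), the stress regulator Nupr1 by 0.97 ± 0.16 (adjusted p 0.0229) and the matricellular Ccn5 by 0.95 ± 0.13 (adjusted p 0.0145). Krt36 fell by 1.73, Prdm8 by 1.32, Pabpc4l by 1.28, Cgref1 by 1.06, Nnat by 1.04 and Pbp2 by 0.96, with Krt36 and Pabpc4l above background on 1 of the 3 IQOS arrays. Atp13a5 passed (adjusted p 0.00677) but was below background in both groups, so its call does not show a change and no fold is given.

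Among these 20 genes the calls of Plaat5, Krtap10-10, Smg8, Cmtm2b and, between background signals, Atp13a5 held without each of the 9 arrays in turn, and 15 did not. Fkbp5 lost its call without air 1 or IQOS 2 (adjusted p up to 0.0561), Fosl1 without any air array (up to 0.076) and Prdm8 and Ccn5 without air 1, air 3 or IQOS 2 (up to 0.0671 and 0.0717). Edn2 lost it without air 1, air 3, IQOS 2 or IQOS 3 (up to 0.0777), Nupr1 without air 1, air 3 or any IQOS array (up to 0.0939) and Nnat without air 1, air 2 or any IQOS array (up to 0.0776). Pbp2 lost it without any air array, IQOS 1 or IQOS 3 (up to 0.0851) and D14Ertd670e without air 1, air 2, CS 2, IQOS 2 or IQOS 3 (up to 0.105). Ramp3 lost it without air 3, CS 2 or any IQOS array (up to 0.0981) and Doc2b without any air array, CS 2, IQOS 1 or IQOS 2 (up to 0.144). Bpifa3 lost it without each of the 9 arrays (up to 0.134), Krt36 without any but CS 1 (up to 0.0911), Cgref1 without any but air 2 (up to 0.146) and Pabpc4l without any but CS 1 and CS 2 (up to 0.101).

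The T and NK cell and the neutrophil lists were higher with IQOS than with air, while the B cell list did not pass (median -0.28, adjusted p 0.602). The helper T cell receptor gene Cd4 rose by 0.66 ± 0.06 (adjusted p 0.00543), and the costimulator gene Icos by 0.78 ± 0.14 (adjusted p 0.0327, lost without air 1, air 3, CS 2 or any IQOS array, up to 0.0981). Of 27 T and NK cell markers 2 rose and 0 fell, 7 and 0 adjusted over the list alone, with 11 at an unadjusted p under 0.05 in limma (median 0.37, adjusted p 0.000395 with the preset and 0.942 with the estimated correlation). The list's median was 0.13 without IQOS 1 (adjusted p 0.191) and 0.56 without IQOS 2. Of 19 neutrophil markers 1 rose and 0 fell, 4 and 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05 in limma (median 0.96, adjusted p 0.000395 with the preset and 0.942 with the estimated correlation). The neutrophil elastase gene Elane rose by 0.77 ± 0.11 (adjusted p 0.0142, up to 0.0671 without air 1 or air 3), while Il1r2 (2.06 ± 0.61) did not pass (adjusted p 0.104). The neutrophil median was 0.63 without IQOS 1, 1.67 without IQOS 2 and 0.61 without IQOS 3. Among 15 glucocorticoid-responsive genes 1 rose, Fkbp5, and 0 fell, the same adjusted over the list alone, with 4 at an unadjusted p under 0.05 in limma (median 0.31, adjusted p 0.0133 with the preset and 0.942 with the estimated correlation). That median was 0.16 without air 1 and 0.16 without IQOS 1 (adjusted p 0.0892). Of 11 goblet cell and mucin genes 0 passed over all genes or over the list alone and 3 had an unadjusted p under 0.05 in limma, with Tff2 at 1.78 ± 0.63, Itln1 at 2.94 ± 1.07 and Fcgbp at 0.67 ± 0.23. The goblet median was 0.67 (adjusted p 0.0298 with the preset and 0.942 with the estimated correlation), and the list did not pass without air 1 (median 0.34, adjusted p 0.132), CS 2 (0.0547), IQOS 2 (0.0581) or IQOS 3 (0.0894). Of 6 cartilage and tracheal gland markers 0 passed over all genes, 3 rose adjusted over the list alone and 3 had an unadjusted p under 0.05 in limma, led by Chad (1.04 ± 0.26, adjusted p 0.0702). Their median was 0.31 (adjusted p 0.0298 with the preset and 0.942 with the estimated correlation), and the list did not pass without air 3 (0.0635), without IQOS 3 (0.0997) or with array row as a covariate (0.0687).

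Cholesterol synthesis, protein folding, matrix and antioxidant lists were lower with IQOS. Of 19 cholesterol synthesis genes 1 fell and 0 rose, 2 and 0 adjusted over the list alone, with 6 at an unadjusted p under 0.05 in limma (median -0.21, adjusted p 0.00594 with the preset and 0.942 with the estimated correlation). The sterol carrier gene Stard4 fell by 0.39 ± 0.07, a call lost without any array but CS 1 (adjusted p up to 0.124). Of 22 unfolded protein response genes 1 fell and 0 rose, 3 and 0 adjusted over the list alone, with 8 at an unadjusted p under 0.05 in limma (median -0.23, adjusted p 0.0133 with the preset and 0.942 with the estimated correlation). The disulfide isomerase gene Pdia6 fell by 0.49 ± 0.10 (adjusted p up to 0.136 without any array but air 3), and the list's median was -0.15 without IQOS 1 and its adjusted p 0.316 without air 2. Of 28 matrix and fibroblast markers 1 fell and 0 rose, the same adjusted over the list alone, with 8 at an unadjusted p under 0.05 in limma (median -0.14, adjusted p 0.0133 with the preset and 0.942 with the estimated correlation, and -0.09 with 0.127 without air 2). The matrix glycoprotein gene Tnc fell by 0.91 ± 0.17, lost without any air or IQOS array (adjusted p up to 0.104). Of 26 NRF2 genes 1 fell and 0 rose, the same adjusted over the list alone, with 6 at an unadjusted p under 0.05 in limma (median -0.16, adjusted p 0.0298 with the preset and 0.942 with the estimated correlation). The glutathione conjugate exporter gene Abcc1 fell by 0.74 ± 0.12 (adjusted p 0.0237, up to 0.0918 without air 1, air 3, IQOS 1 or IQOS 2). The NRF2 median was -0.09 without IQOS 1 (adjusted p 0.255) and -0.28 without IQOS 3, and the list missed the threshold without IQOS 2 (0.0592).

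With IQOS, Cyp1a1 changed by 2.27 ± 1.09 (adjusted p 0.273) and did not pass, and by 0.73 ± 0.17 without IQOS 3, whose signal lay above those of the other IQOS arrays. Cyp1b1 changed by 1.13 ± 0.27 (adjusted p 0.0604). Nqo1 changed by -0.11 ± 0.41, Gpnmb by 0.03 ± 0.18 and Mmp12 by -0.12 ± 0.40 (adjusted p 0.904, 0.931 and 0.891). Their directions flipped, that of Nqo1 with array row as a covariate, that of Gpnmb with normexp background correction and all 3 without single arrays. Of 15 AhR and phase I genes 0 passed over all genes, 2 rose adjusted over the list alone and 4 had an unadjusted p under 0.05 in limma (list adjusted p 0.557). Of 25 lysosomal macrophage genes and of 26 cytokine genes 0 passed over all genes or over the list alone, with 2 and 3 at an unadjusted p under 0.05 in limma (list adjusted p 0.693 and 0.557).

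Among 34 proapoptotic genes with IQOS, 1 rose and 1 fell, the same adjusted over the list alone (list median -0.03 against a mean of 0.00, adjusted p 0.693). Trp53 fell by 0.41 ± 0.07 (adjusted p 0.0248, up to 0.0976 without any air or IQOS array and 0.0824 with array row as a covariate) and the p53-induced death domain gene Pidd1 rose by 0.54 ± 0.10 (adjusted p 0.0354, up to 0.11 without any array but IQOS 1). Bax changed by -0.06 ± 0.07 (adjusted p 0.654), Fas by 0.02 ± 0.12 (adjusted p 0.927), Bcl2 by 0.04 ± 0.23 (adjusted p 0.945) and Cdkn1a by 0.79 ± 0.33 (adjusted p 0.213), with none passing. The direction flipped with normexp background correction for Bax and Fas, with median centring for Fas, and with the mean of all probes for Bcl2. Of 19 antiapoptotic and 22 p53 target genes 0 passed over all genes or over the list alone, with 4 and 6 at an unadjusted p under 0.05 in limma (list adjusted p 0.247 and 0.693). Pim1 changed by 0.38 ± 0.11 (adjusted p 0.101).

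In limma 1387 probes passed between IQOS and air, 1022 higher and 365 lower, for 643 genes with a symbol, and 95 changed at least 2-fold, 85 higher and 10 lower. The count and balance moved with the setting, with 1433 higher and 1188 lower with normexp background correction, 525 and 255 with median centring and 370 and 74 from the 6 arrays compared. All called probes had groups that did not overlap, as did 29.1% of all probes where chance gives 10%. Probes without a gene symbol were 34.9% of those tested and 62.2% of those called higher. The count was 124 without air 1, 703 without air 2, 312 without air 3, 661 without CS 2, 643 without IQOS 1, 161 without IQOS 2 and 512 without IQOS 3. Of the 35 called genes named by rule 6, Plaat5, Krtap10-10, Smg8, Cmtm2b, Cd4 and, between background signals, Atp13a5, kept their call without each array. It was 77 without both air 2 and IQOS 3 and 287 with array row as a covariate, where 11 of the 35 genes kept their call. Slide could not be a covariate because all IQOS arrays share 1 slide with no other group.

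The comparison of IQOS with CS contrasts the groups of the 2 aerosols directly, but slide and array row differ between their arrays as well. The differences below therefore cannot be told apart from those of slide and row. AhR targets were among the largest differences. Cyp1a1 was lower with IQOS by -6.64 ± 1.09 on the log2 scale (adjusted p 0.013), Cyp1b1 by -4.36 ± 0.27 (adjusted p 0.000524) and Ahrr by -5.63 ± 0.32 (adjusted p 0.000371, above background on 1 of 3 IQOS arrays). The size of the Ahrr difference is uncertain, since it rests in part on background signals. Of 15 AhR and phase I genes 6 were lower and 0 higher, 10 and 1 adjusted over the list alone, with 11 at an unadjusted p under 0.05 in limma (median -0.34, adjusted p 5.52e-05 with the preset and 0.46 with the estimated correlation). Of 26 NRF2 genes 16 were lower and 1 higher, 23 and 1 adjusted over the list alone (median -0.81, adjusted p 2.66e-11 with the preset and 0.472 with the estimated correlation). Nqo1 differed by -2.67 ± 0.41 (adjusted p 0.0108), Txnrd1 by -1.31 ± 0.15, Akr1b8 by -1.65 ± 0.25 and Gstp1 by -0.78 ± 0.08. The higher gene, Gstm2 (0.38), was named after its value was seen. Mt1 and Mt2 were lower by -1.27 ± 0.11 and -1.56 ± 0.14.

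Other genes among the 10 largest negative differences were Awat1 (at least 13.6-fold lower) and Moxd2 (at least 12.2-fold lower, with 2 CS arrays), neither well above background in IQOS. They also included Cd200r2 (-4.90 ± 0.45, above background on 1 of 3 IQOS arrays), Cd177 (-4.45 ± 0.96), the nuclear receptor gene Hnf4a (-4.30 ± 0.53), the growth factor gene Ereg (-4.07 ± 0.43) and Btbd17 (-3.67 ± 0.75). The last 4 were above background on 2 of 3 IQOS arrays. The largest positive differences were in Gmnc (at least 2.37-fold, not well above background in CS), Plaat5 (2.60 ± 0.26, adjusted p 0.00277), Cyp26b1 (2.39 ± 0.45, adjusted p 0.02), Spon2 (2.18 ± 0.51) and the clock gene Arntl (2.17 ± 0.53, adjusted p 0.0436). Next came Kcna1 (2.01 ± 0.33, above background on 1 of 3 CS arrays), Fabp1 (1.83 ± 0.21), D14Ertd670e (1.82 ± 0.33), Shisa3 (1.80 ± 0.30, above background on 2 of 3 CS arrays) and Hcar1 (at least 1.15-fold, not well above background in CS). Of the 20 genes 13 kept their call without each array in turn. The calls ended for Cyp26b1 without CS 3, IQOS 1 or IQOS 2 (adjusted p up to 0.0618) and D14Ertd670e without CS 2, CS 3 or IQOS 2 (up to 0.0582). They ended for Btbd17 without CS 2, CS 3 or IQOS 2 (up to 0.0769) and Cd177 without any CS array, IQOS 2 or IQOS 3 (up to 0.0832). They ended for Spon2 and Arntl without any array but air 2 and air 3 (up to 0.105 and 0.124) and for Hcar1 without any array but air 2 and CS 1 (up to 0.0942). Within the air group alone the signal of Arntl ranged from -1.48 to 0.74. The 17 clock genes did not pass as a list (median -0.47, camera adjusted p 0.0643 with the preset correlation). In that list 4 genes were lower and 1 higher, 4 and 3 adjusted over the list alone.

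The lysosomal and alveolar macrophage, cytokine, protease and neutrophil lists were lower with IQOS than with CS. Gpnmb differed by -2.12 ± 0.18 (adjusted p 0.00175), Ctsk by -2.04 ± 0.17 (adjusted p 0.00172), the proton pump subunit gene Atp6v0d2 by -1.56 ± 0.12 and Ctsd by -0.92 ± 0.07. Of 25 lysosomal macrophage genes 16 were lower and 1 higher, 20 and 1 adjusted over the list alone (median -0.50, adjusted p 1.38e-12 with the preset and 0.347 with the estimated correlation). The higher one, the scavenger receptor gene Cd36 (0.36), was named after its value was seen. Of 19 alveolar macrophage markers 9 were lower, among them Itgax (-1.02 ± 0.09) and Mrc1 (-0.65 ± 0.08), and 1, Fabp1, was higher, 10 and 1 adjusted over the list alone (median -0.37, adjusted p 0.00118 with the preset and 0.46 with the estimated correlation). Of 26 cytokine genes 10 were lower and 0 higher, 14 and 1 adjusted over the list alone, with 16 at an unadjusted p under 0.05 in limma (median -0.90, adjusted p 8.04e-06 with the preset and 0.46 with the estimated correlation). Il6 differed by -2.47 ± 0.36, Cxcl1 by -2.02 ± 0.31, Cxcl2 by -1.98 ± 0.25 and Ccl6 by -1.29 ± 0.13. Mmp12 (-1.36 ± 0.40) did not pass (adjusted p 0.0691). Of 24 elastin-degrading proteases and inhibitors 5 were lower and 1 higher, 9 and 1 adjusted over the list alone (median -0.49, adjusted p 0.044 with the preset and 0.65 with the estimated correlation). Timp3 was lower (-0.46 ± 0.07) and Elane was higher (0.68 ± 0.11). The protease list did not pass without air 2 (adjusted p 0.0639), air 3 (0.0755), CS 3 (0.0745), IQOS 1 (0.0591) or IQOS 2 (0.0901) or with array row as a covariate (0.935). Elane was also the gene called among 19 neutrophil markers, 1 higher and 0 lower, the same adjusted over the list alone, with 2 at an unadjusted p under 0.05 in limma. The list's median was -0.60 (adjusted p 0.0481 with the preset and 0.826 with the estimated correlation). The neutrophil median was -1.16 without CS 1, -0.39 without CS 3 (adjusted p 0.226) and -0.40 without IQOS 2 (0.417). The list missed the threshold without air 2 (0.0601), air 3 (0.0525) or CS 2 (0.0801) and with array row as a covariate (0.58).

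The matrix, smooth muscle, endothelial and cartilage lists were higher with IQOS than with CS. Fbn1 differed by 0.68 ± 0.08 (adjusted p 0.0037), Loxl1 by 0.73 ± 0.12 and the elastin gene Eln by 0.92 ± 0.17 (adjusted p 0.017, and 0.0515 without CS 3). Of 28 matrix markers 6 were higher and 0 lower, the same adjusted over the list alone, with 8 at an unadjusted p under 0.05 in limma (median 0.24, 0.13 without CS 3, adjusted p 0.00772 with the preset and 0.826 with the estimated correlation, and 0.107 with array row as a covariate). Of 14 smooth muscle markers Lmod1 (0.66 ± 0.08) was higher and 0 lower, 2 and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05 in limma (median 0.19, adjusted p 0.0349 with the preset and 0.826 with the estimated correlation). That list did not pass without CS 3 (median 0.11, adjusted p 0.201), without IQOS 2 (0.102) or with array row as a covariate (0.0596). Of 27 endothelial markers 3 were higher, among them Aplnr (0.92 ± 0.13), and 1, Bmx (-0.51, lost without CS 2, CS 3 or any IQOS array, adjusted p up to 0.094), was lower, the same adjusted over the list alone. The endothelial median was 0.16 (adjusted p 0.0364 with the preset and 0.826 with the estimated correlation), and -0.05 with array row as a covariate (adjusted p 0.796). The list did not pass without CS 1 (0.0592), IQOS 1 (0.089) or IQOS 2 (0.0513). Of 6 cartilage and tracheal gland markers the collagen gene Col2a1 (1.13 ± 0.12) was higher and 0 lower, 2 and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05 in limma (median 0.46, adjusted p 0.0235 with the preset and 0.46 with the estimated correlation, 0.054 without IQOS 3 and 0.232 with array row as a covariate).

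The cholesterol synthesis, alveolar type II, immediate early and autophagy lists were lower with IQOS than with CS. Of 19 cholesterol synthesis genes 4 were lower and 0 higher, 7 and 0 adjusted over the list alone, with 12 at an unadjusted p under 0.05 in limma (median -0.31, adjusted p 0.000189 with the preset, 0.684 with the estimated correlation and 0.145 with array row as a covariate). The squalene synthase gene Fdft1 differed by -0.50 ± 0.12 (adjusted p 0.0367, up to 0.101 without any array but air 3 and IQOS 3). Of 20 alveolar type II markers 3 were lower and 0 higher, 6 and 1 adjusted over the list alone, with 9 at an unadjusted p under 0.05 in limma (median -0.16, -0.25 without IQOS 2, adjusted p 0.00591 with the preset, 0.826 with the estimated correlation and 0.0633 with array row as a covariate). Il33 differed by -1.03 ± 0.17. Of 20 immediate early genes 3 were lower and 0 higher, the same adjusted over the list alone, with 6 at an unadjusted p under 0.05 in limma (median -0.28, adjusted p 0.0124 with the preset and 0.826 with the estimated correlation). Fosl1 differed by -3.09 ± 0.43 (above background on 2 of 3 IQOS arrays) and Ier3 by -1.08 ± 0.13. The immediate early median was -0.09 without CS 1 (adjusted p 0.157), -0.44 without IQOS 1 and -0.03 without IQOS 3 (0.308). Of 24 autophagy genes Lamp2 (-0.22) was lower and 0 higher, 0 adjusted over the list alone and 7 at an unadjusted p under 0.05 in limma (median -0.09, adjusted p 0.025 with the preset and 0.604 with the estimated correlation). Lamp2 lost its call without any array but CS 1 (adjusted p up to 0.124), and the list without CS 3 (0.0697) or IQOS 3 (0.0566).

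Of 18 B cell markers the transcription factor gene Spib (1.5 ± 0.36) was higher in IQOS than in CS and 0 lower, 0 adjusted over the list alone and 9 at an unadjusted p under 0.05 in limma (median 0.63, adjusted p 0.0124 with the preset, 0.826 with the estimated correlation and 0.0714 without IQOS 3). Spib lost its call without air 1, air 3, CS 2, CS 3, IQOS 1 or IQOS 3 (adjusted p up to 0.116). Of 10 thymus and lymph node markers Glycam1 (0.52 ± 0.08) and the chemokine gene Ccl21a (0.59 ± 0.14) were higher and 0 lower, 5 and 0 adjusted over the list alone, with 6 at an unadjusted p under 0.05 in limma (median 0.47, adjusted p 0.0481 with the preset and 0.57 with the estimated correlation). Ccl21a lost its call without any array but air 2 (adjusted p up to 0.108), and the list did not pass without air 3 (0.0636), CS 2 (0.0801), CS 3 (0.0859), IQOS 1 (0.0768) or IQOS 3 (0.106) or with array row as a covariate (0.0697). Of 15 cardiac muscle markers 0 passed over all genes or over the list alone and 1 had an unadjusted p under 0.05 in limma (median 0.54, adjusted p 0.0124 with the preset and 0.826 with the estimated correlation). The cardiac median was 0.26 without CS 3 (adjusted p 0.134) and 0.32 without IQOS 3 (0.119).

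Apoptosis genes were also compared between IQOS and CS, where 4.38% of all tested probes with a symbol were called higher and 4.89% lower. Of 34 proapoptotic genes 0 passed over all genes or over the list alone and 3 had an unadjusted p under 0.05 in limma (list adjusted p 0.522). Bax differed by -0.11 ± 0.07 (adjusted p 0.337), Fas by 0.00 ± 0.12 (adjusted p 0.997), Bcl2 by 0.29 ± 0.23 (adjusted p 0.448) and Cdkn1a by 0.38 ± 0.33 (adjusted p 0.486). The directions flipped for Fas with normexp background correction, median centring or the mean of all probes and for Cdkn1a with array row as a covariate. Of 19 antiapoptotic genes 3 were lower and 1 higher, 3 and 2 adjusted over the list alone (list adjusted p 0.261). The lower ones were Pim1 (-0.63 ± 0.11, lost without CS 3 or IQOS 1, adjusted p up to 0.0521), Bcl2a1d (-0.49, lost without CS 3, IQOS 1 or IQOS 2, up to 0.0865) and Birc3 (-0.51, lost without any array but IQOS 1, up to 0.109), and the higher one was Bag4 (0.41, lost without CS 1, CS 3 or any IQOS array, up to 0.0839). Of 22 p53 target genes Eda2r (1.18 ± 0.30, above background on 2 of 3 CS arrays) was higher and 0 lower, 0 adjusted over the list alone and 11 at an unadjusted p under 0.05 in limma (list adjusted p 0.645). Eda2r lost its call without any array but CS 1 and CS 3 (adjusted p up to 0.119), and its difference was 0.78 without CS 1.

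In limma 3590 probes passed between IQOS and CS, 2126 higher and 1464 lower, for 2012 genes with a symbol, and 440 differed at least 2-fold. The balance turned with the setting, with 185 higher and 255 lower at a minimum of 2-fold, 2396 and 2462 with normexp background correction, and 1123 and 1267 over probes with a symbol. All called probes had groups that did not overlap, as did 32.8% of all probes where chance gives 10%. The count was 2212 without air 1, 1273 without CS 2, 1617 without CS 3, 1597 without IQOS 1, 1420 without IQOS 2 and 2089 without IQOS 3. Of the 87 called genes named by rule 47 kept their call without each array. It was 1557 without both air 2 and IQOS 3 and 83 with array row as a covariate, where 4 of the 87 genes, Cyp1b1, Ahrr, Awat1 and Moxd2, kept their call. In that fit the row term came from the air arrays alone, since every CS array lay in row 2 and every IQOS array in row 1. The lost calls therefore do not show that row caused the differences. Slide, array row and aerosol cannot be told apart in this comparison.

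**Figure D3:**
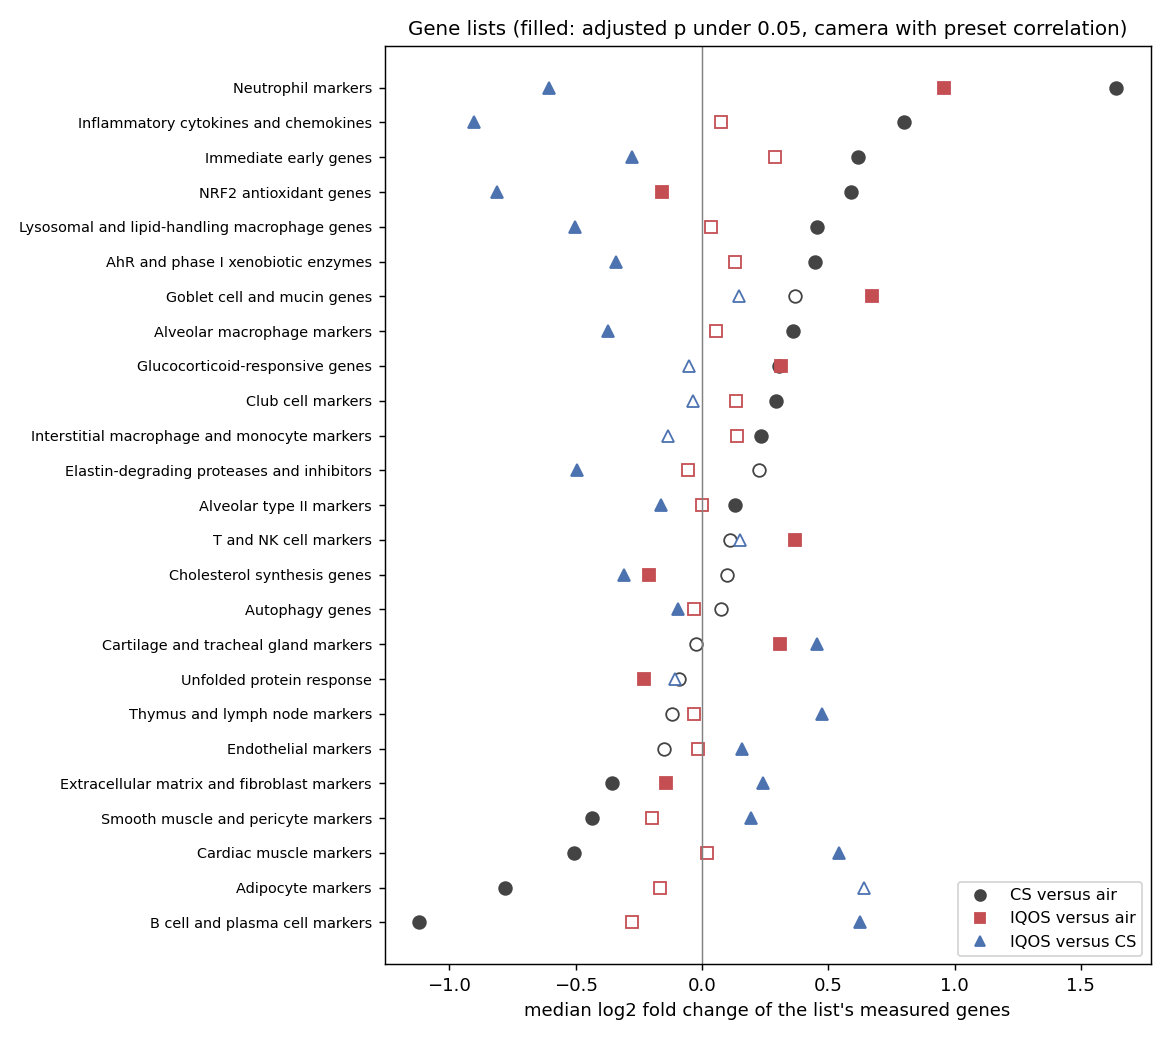
Median log2 fold change (x axis) of the gene lists (y axis) in the 3 comparisons CS versus air, IQOS versus air and IQOS versus CS, with filled points where the adjusted p of camera with the preset correlation was under 0.05. The lysosomal macrophage list lies at 0.45 for CS versus air, 0.03 for IQOS versus air and -0.50 for IQOS versus CS.

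Some genes were called with both aerosols against the shared air arrays. Fkbp5 rose by 1.64 with CS and 1.46 with IQOS, Nupr1 fell by 1.67 and 0.97, and Trp53 fell by 0.50 and 0.41. Of the genes with a symbol called in both, 44 were higher in both, 66 lower in both and 7 went opposite ways. The last include Atp13a5, whose call with IQOS lay between background signals. Among probes, 126 were higher in both where independent lists would share 47.3, 200 were lower in both where they would share 20.7, and 20 went opposite ways. Those expected values leave out the shared air arrays. In 20 simulated draws of unchanged groups against the same air arrays at most 0 called probes were shared. With no changed probes hardly any are called, so that result was near certain beforehand. It does not measure how much the shared air arrays add to the overlap. Across 37258 probes, which are not independent replicates, the correlation of the CS and IQOS changes was 0.457, against 0.501 (range 0.476 to 0.525) in 100 simulated draws of unchanged groups compared with the same air arrays. Their covariance was 0.0523 against a simulated 0.016, a difference of 0.0363. The 3 air arrays are too few to give each comparison 2 of its own, so part of the excess may come from the shared controls.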

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

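The alternatives without air 2 and IQOS 3 together and with symbol-bearing probes alone were chosen after seeing the data. Without 1 array the probe count ranged from 725 to 3303 for genes changed, CS versus air, from 124 to 1095 for genes changed, IQOS versus air, and from 1273 to 3214 for genes changed, IQOS versus CS, and fewer arrays leave fewer degrees of freedom. For CS against air, IQOS against air and IQOS against CS in that order, the counts were 1541, 356 and 1658 with no filter on dim probes, where more probes were tested, and 311, 287 and 83 with array row as a covariate, which leaves air 3 as the only air array in the row of the CS arrays. They were 575, 95 and 440 at a minimum of 2-fold, 7098, 3281 and 6523 at an adjusted p under 0.1, and 1513, 77 and 1557 without both air 2 and IQOS 3. For IQOS against air alone the count rose to 2621 with normexp background correction, where 54.7% of calls were higher instead of 73.7%, and was 780 with median centring, 444 from the 6 arrays compared and 468 over probes with a symbol. For IQOS against CS the last 2 gave 1769 and 2390. The cause of the normexp and median centring shifts was not tested. All other probe counts under quantile normalization, the filter on all 9 arrays, the series matrix values and the intensity trend stayed within 1.5 times their value. With camera and an estimated correlation 0, 0 and 0 lists passed, with 4, 1 and 4 of 45 at an unadjusted p under 0.05. The list counts stayed within 1.5 times under every other setting. Of the 43 list calls over the comparisons, 30 kept their direction and side of the threshold with array row as a covariate, 31 without both air 2 and IQOS 3, 36 with no filter, 37 with normexp, 40 with quantile normalization, 41 with median centring and 43 with the series matrix values. Of 250 values of genes named by rule, 56 did so with array row as a covariate, 150 with no filter, 229 with median centring, 236 with normexp and 243 with the series matrix values.

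With the replicate number as a block (replicate block) 3249, 540 and 2722 probes passed. Whether the numbers pair the arrays cannot be settled with 3 arrays per group. After removing group means, same-numbered arrays of air and CS correlated at -0.0789, -0.0408 and -0.0625. Those of air and IQOS correlated at 0.0793, 0.201 and 0.168, and those of CS and IQOS at 0.132, 0.00938 and 0.161. As a hint from the data alone, each air and IQOS array correlated best with its own number in the other group, but between air and CS none did, and air 1 reached 0.105 with CS 3. With the block 194 of the 250 gene values and 42 of the 43 list calls kept their direction and side of the threshold, and no reported direction changed.

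Directions that reversed belonged, with 2 exceptions, to genes that were not called. With normexp background correction the log2 change was 0.0674 for Bax, IQOS versus air, -0.0522 for Fas, IQOS versus air, -0.0273 for Gpnmb, IQOS versus air, and -0.0697 for Fas, IQOS versus CS. Quantile normalization gave -0.00572 for Fas, CS versus air, and median centring -0.00822 for Fas, IQOS versus air, and -0.024 for Fas, IQOS versus CS. Array row as a covariate gave -0.00497 for Fas, CS versus air, 0.054 for Nqo1, IQOS versus air, -0.00877 for Bcl2, IQOS versus air, -0.248 for Cdkn1a, IQOS versus CS, and -0.0513 for the median of list Endothelial markers, IQOS versus CS, which had passed. The mean of all probes gave -0.00216 for Bax, CS versus air, -0.0403 for Bcl2, IQOS versus air, -0.0092 for Fas, IQOS versus CS, and 0.402 for Stard4, CS versus air, which had been called as lower. Without 1 array, values on both sides of 0 ranged from -0.0351 to 0.0736 for Fas, CS versus air, -0.105 to 0.1001 for Fas, IQOS versus air, -0.129 to 0.0765 for Fas, IQOS versus CS, -0.103 to 0.122 for Gpnmb, IQOS versus air, -0.611 to 0.186 for Nqo1, IQOS versus air, -0.175 to 0.217 for Bcl2, IQOS versus air, and -0.362 to 0.0621 for Mmp12, IQOS versus air. The cause of these reversals was not tested. The correlation of CS and IQOS effects was 0.393 with no filter, 0.268 with array row as a covariate and 0.39 to 0.528 without 1 array. Beyond the settings, signal over background limits what the dim probes can show.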

Other observations

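The tests chosen only after the result was seen were those of CS-lung RNA in IQOS 3, of dilution by leukocyte RNA, of array row by the spread between arrays and of the slide for higher and lower probes apart. Some genes varied between arrays of 1 group. On air 2 the clock output gene Dbp lay at 1.74 on the log2 scale against 4.73 and 4.74 on the other air arrays, and its regulator Arntl at 0.74 against -0.995 and -1.48. Dbp lay at 2.72, 2.67 and 3.53 in IQOS and at 4.2, 4.22 and 3.4 in CS. Arntl lay at 0.11, 0.66 and 0.02 in IQOS and at -2.18, -2.16 and -1.36 in CS. The neutrophil alarmin gene S100a8 lay at 5.83, 6.84 and 7.53 in CS and at 6.33, 3.94 and 6.34 in IQOS, against 4.25, 4.33 and 4.98 in air. The protease inhibitor gene Serpina1a lay at -0.24 on air 3 against -4.01 and -5.01, and Cxcl9 at -1.24 on IQOS 3 against -3.88 and -3.97. These genes were picked after their values were seen.

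The IQOS arrays alone lay on the second slide, so slide and IQOS cannot be told apart. Over all probes called between IQOS and air, the median of the CS change divided by the IQOS change was 0.295, where unchanged CS arrays gave up to 0.095 in simulations. For the probes called higher it was 0.192 (0.265 for those with a symbol and 0.149 for those without), low but above the 0.0843 that unchanged CS arrays gave at most in simulations, so it does not decide. For those called lower it was 0.762, so the CS arrays, which share the slide of the air arrays, were typically lower there as well. Both changes subtract the same air arrays, which alone can raise the ratio, so it does not exclude the slide. The simulations took the observed IQOS changes as real, so they may understate the ratio that the shared air arrays alone give. The calls also depended on the air arrays, with 114 higher and 10 lower without air 1. Labelling or hybridisation stays open. The 10 spike-in probes differed by a median of 0.024 against 0.462 for the called probes, under the bound set before. That bound was wrong, since 3.72% of tested probes were called, and at that rate 0.372 of the 10 would be affected, too few to move their median.

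Cyp1a1 was high on IQOS 3 alone (3.09 against -1.58 and -1.46). CS-lung RNA in that sample may be a cause and would need a share of 8.11%. The 5 precisely measured genes at least 4-fold higher with CS gave a median share of 1.55% with a highest upper value of 5.83%, below the share needed. They were picked by their small spread after the result was seen, and Awat1 and Ahrr among them were not well above background in air. Over all 56 such genes the median share was 6.21% (2.21 to 12.3 over the genes), which does not exclude 8.11%. CS-lung RNA as a cause therefore stays open. A response of the whole IQOS group stays open, since the values without IQOS 3 do not decide. Cyp1a1 then changed by 0.732 (95% interval 0.329 to 1.13) and Cyp1b1 by 0.815 (0.395 to 1.24), but neither passed (adjusted p 0.0859 and 0.0767). In the same fit Aldh3a1 changed by 0.181 and Nqo1 by -0.611. Ahrr changed by 0.0585 (-0.543 to 0.66). Its air signal was not well above background, so a small rise could be hidden. A rise as large as that with CS was not seen on these IQOS arrays.

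The matrix and smooth muscle lists were lower with CS. Dilution by leukocyte RNA would lower alveolar type I markers as well, but their median was 0.0116 against -0.356 for the matrix list. The interval of the type I median, -0.0952 to 0.0615, was taken over its genes and leaves out the spread between arrays. Per array, relative to air, the type I median lay at 0.0331, 0.0272 and -0.0366 in CS and at 0.000207, 0.0722 and -0.088 in air. The matrix median lay at -0.33, -0.229 and -0.543 in CS and at -0.0474, 0.11 and -0.0446 in air. These values argue against dilution as the whole cause. Other lists moved both ways, with medians of -1.12 for B cell, -0.777 for adipocyte, -0.508 for cardiac and -0.15 for endothelial markers and of 0.132 for alveolar type II and 0.293 for club cell markers. The endothelial list did not pass, none passed with an estimated correlation (adjusted p at least 0.713), and with array row as a covariate the adipocyte and alveolar type II lists did not (0.314 and 0.0544). With array row as a covariate both lists passed, the matrix list at -0.418 (-0.604 to -0.0733 over its genes, adjusted p 0.000155) and the smooth muscle list at -0.453 (adjusted p 0.000709), both with the preset correlation. With the estimated one and without row neither passed (adjusted p 0.664 for each). Row may still contribute and stays open, since air 3 alone shares the row of the CS arrays. By the spread between arrays, the matrix difference per array was -0.323 (95% interval -0.658 to 0.0132) with row and -0.373 (-0.586 to -0.161) without it. The smooth muscle difference was -0.465 (-0.965 to 0.0345) with row and -0.459 (-0.766 to -0.152) without it. CS 3 had the lowest median of all arrays, relative to air, in the matrix (-0.543), smooth muscle (-0.706), adipocyte (-1.31) and cardiac (-1.05) lists. Why these lists were lowest on the same array was not tested. A response of the tissue to smoke was not tested apart from dilution and array row.

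With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split, refitted with limma on the 6 arrays over the probes kept for all 9, gave 2722 probes for CS against air with 1 as the highest of the other splits, 408 for IQOS against air with 0, and 1710 for IQOS against CS with 0, and 1 of the 10 splits gave as many in each comparison.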
